A study of Mus musculus with 14 samples.

How the data were processed

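The deposited table held FPKM values, computed by the authors with Cufflinks, for 22255 Ensembl genes in 14 libraries made with Smart-Seq2 from low-input total RNA. The submitters' processing notes name Trimmomatic, TopHat2 2.1.1, Bowtie2 2.2.9, Cuffdiff, Cufflinks 2.2.1 and DESeq2 on mm10 (GRCm38). None of these was rerun. Gene names, biotypes and positions came from GENCODE M21 on GRCm38. Of the 22255 identifiers 22196 matched it and 59 did not, and 33254 of the 55450 M21 genes, 2973 of 21951 protein-coding ones among them, have later identifiers than any in the table and are not analysed here. The plan assumed read counts first. The unit is FPKM, so the branch written for it, limma-trend on log2(FPKM + 1), was used. The steps between low values multiplied by transcript length, in genes with a single annotated transcript, gave the reads per library. Of these low values 92.8 to 95.7% (197 to 347 values per library, up to 20 reads, genes of at least 0.8 kb) were whole reads within 0.1. FPKM totals ran from 492605 to 595391.

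Groups, comparisons, tests, gene lists and the rule for named genes were set before the data were examined. A gene was tested where at least 3 of the libraries in the fit reached 1 FPKM, which left 9616 genes in the fit of the 11 spleen, LN and WT tumor libraries and 8210 in the fit of the 6 tumor libraries. Robust limma-trend (limma 3.58.1, R 4.3.3) gave log2 differences with standard errors, and Benjamini-Hochberg adjustment within a comparison took adjusted p of 0.05 as threshold. Differences are on the log2(FPKM + 1) scale, which understates those of genes with low levels. Levels are means ± SD, and values of each library where a library is listed at 0. FPKM are shares, so a gain in some genes lowers others. Scaling to the protein-coding total (outside the mitochondrial genome and globin genes) moved the median of all genes by less than 0.1 in each comparison. The 3-read limits cover counting error only. The standard errors and SDs measure the spread between libraries.

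The 23 lists were lipid uptake and storage, fatty acid oxidation, PPAR receptors, partners and targets, nuclear and mitochondrial oxidative phosphorylation genes, mitochondrial biogenesis and dynamics, TCA cycle, glycolysis, cholesterol synthesis, fatty acid synthesis, Treg core signature, effector and tumor Treg genes, resting and central Treg genes, chemokines and their receptors, T cell receptor and NF-kB response, cell cycle, apoptosis-promoting, apoptosis-opposing, hypoxia response, type I interferon response, unfolded protein and integrated stress response, immediate early and heat shock genes (known to follow cell isolation), and cytoplasmic ribosomal proteins. Each with at least 3 tested members entered camera with a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Camera with the correlation estimated per list, and fry, were run beside it. Calls of members are limma calls over all tested genes. Counts adjusted over the list alone repeat the adjustment within the list. Markers of macrophages or monocytes, dendritic cells, neutrophils, B cells, CD8 T or NK cells, conventional helper T cells, fibroblasts or endothelial cells, erythroid cells and melanoma cells were scored as the mean log2(FPKM + 1), with exact permutation tests. A check of sex-linked genes gave scores from 0.00340 to 0.0490 in all libraries.

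The rule for named genes took, per comparison, Cd36 and Foxp3, up to 6 genes each way with the largest log2 difference among those past the threshold with at least 10 FPKM and no overlap between groups (no predicted genes or receptor segments), the 2 members of each list with the smallest p, 4 for each list past camera, and the 2 highest of each other-cell list. The text names a part of these, picked for room after the values were seen. Overlap and covariance were set against 100 simulations of unchanged groups, drawn with each group's own SD, that share the WT tumor libraries. In 10 simulations of 200 changed genes each, the gene test recovered 4.18, 4.18, 4.78 and 1.19% of changes of 2 times, and 73.8, 73.8, 79.4 and 52.9% of changes of 16 times (WT tumor against spleen, WT tumor against LN, LN against spleen, KO against WT tumor), with 5.86, 6.23, 7.15 and 1.40% false calls. A shifted list was found in all 10 simulations with the preset correlation and in 9, 10, 10 and 7 with an estimated one. Of 220 unshifted lists 5, 7, 4 and 6 were called with the preset and 1, 3, 1 and 0 with the estimated correlation. All these simulations, those of overlap and covariance included, drew each gene independently. They do not measure false list calls where members move together. The mitochondrial respiratory chain list, for one, had an estimated correlation of 0.327 for WT tumor against spleen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 did the rest.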

Results

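Regulatory T cells (Tregs), the CD4 T cells that restrain immune responses under the transcription factor Foxp3, were compared in 14 RNA libraries from 8-week-old mice. The cells were Foxp3-YFP-positive. They came from spleen (4 libraries), lymph node (LN, 4), tumors of wild-type Foxp3-YFP-Cre mice (WT tumor, 3, replicates 2, 3 and 4) and tumors of mice that carry floxed Cd36 with Foxp3-YFP-Cre (KO tumor, 3). Cd36 encodes a scavenger receptor that takes up long-chain fatty acids and oxidized lipids. Read depths estimated from the steps between low values were 13.2, 12.3, 27.6 and 23.0 M reads in spleen 1 to 4 (M, mega) and 21.3, 20.3, 21.5 and 18.3 M in LN 1 to 4. They were 10.7, 26.9 and 14.4 M in WT tumor 2 to 4, and 16.8, 13.6 and 17.2 M in KO tumor 1 to 3. Between 7469 and 8307 genes per library reached 1 FPKM. The replicates are not said to be separate animals, so the p-values measure only the spread between these samples, which may be technical. Tumor type, preparation dates and the steps of cell isolation are not given in the sources used here.

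Cd36, the targeted gene (chromosome 5, 17781690 to 17888801, GRCm38), was detected in 3 of 4 spleen libraries and 1 KO tumor library, and was listed at 0 in all LN and WT tumor libraries. Its FPKM values were 0, 0.598, 4.47 and 2.17 in spleen 1 to 4, and 0, 1.06 and 0 in KO tumor 1 to 3. In the same libraries 3 reads over its 3399 bp transcript would give 0.0320 to 0.0822 FPKM, so a level above that was not seen in any WT tumor library. The log2(FPKM + 1) difference was -1.198 for WT tumor against spleen (exact p = 0.257, n = 3 and 4). It was -1.198 for LN against spleen (exact p = 0.143, n = 4 and 4) and 0.35 for KO against WT tumor (exact p = 1, n = 3 and 3). Without spleen replicate 1 the LN against spleen difference was -1.60 (exact p = 0.0286), and without KO tumor replicate 2 the KO against WT tumor difference was 0. Loss of Cd36 could thus not be read from the KO libraries, where the WT level was already 0, and reads from exons outside the floxed part would still be counted. Spleen and KO tumor, the only groups with Cd36 reads, also had the higher macrophage marker scores (below). These were 3.42, 3.05, 2.84 and 2.61 in spleen 1 to 4 and 3.02, 2.71 and 2.40 in KO tumor 1 to 3. LN and WT tumor libraries scored 0.560 to 1.53. Whether the Cd36 reads came from Tregs or from other cells was not tested. Foxp3 (chromosome X, 7573644 to 7595245) was present in every library, at 36.6 ± 9.42 (KO tumor) and 9.16 ± 4.86 FPKM (WT tumor, mean ± SD). It stood at 18.6 ± 8.00 FPKM in spleen and 24.2 ± 6.95 FPKM in LN. It passed the threshold in none of the 4 comparisons: the limma estimate was 2.01 ± 0.61, adjusted p = 0.338 for KO against WT tumor and -0.99 ± 0.55, adjusted p = 0.448 for WT tumor against spleen. Those against LN and between LN and spleen were -1.42 ± 0.55, adjusted p = 0.223, and 0.42 ± 0.51, adjusted p = 0.851.

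**Figure D1:**
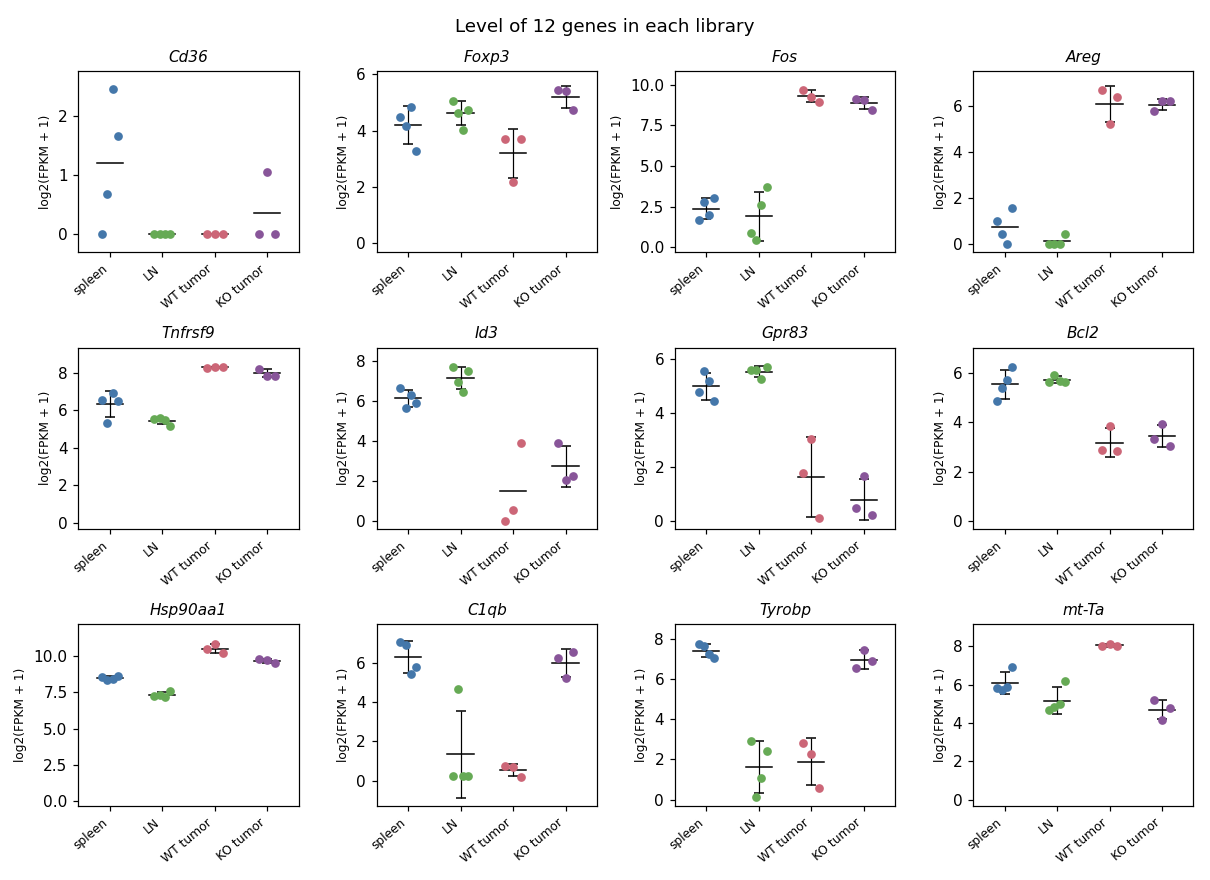
Level of 12 genes (y axis, log2(FPKM + 1)) in each library of spleen (4), LN (4), WT tumor (3) and KO tumor (3). Points are libraries, horizontal lines group means, and vertical bars the SD, drawn only where no library of the group is listed at 0.

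In the comparison of tissues, the first question of the series, WT tumor Tregs had higher levels of immediate early genes, of the receptor genes Tnfrsf9 and Icos and of the growth factor gene Areg than spleen Tregs (n = 3 and 4). Fos, an AP-1 subunit induced within minutes of stimulation (chromosome 12, 85473890 to 85477273), had a log2(FPKM + 1) difference of 6.93 ± 0.72 (SE), limma adjusted p = 0.000405. Its levels were 637 ± 164 against 4.53 ± 2.38 FPKM. Areg, the tissue-repair growth factor amphiregulin (chromosome 5, 91139599 to 91148432), rose by 5.35 ± 0.61, adjusted p = 0.000724. It stood at 102, 35.8 and 83.1 FPKM in WT tumor and 0.998, 0.335, 0 and 1.94 in spleen. The RNA for Tnfrsf9 (4-1BB) rose by 1.97 ± 0.35, adjusted p = 0.0114, 309 ± 3.59 against 84.3 ± 33.2 FPKM. That for Icos rose by 1.38 ± 0.20, adjusted p = 0.00273, 767 ± 56.4 against 299 ± 70.5 FPKM. Both are receptors of activated Tregs. On the other side was Id3, an inhibitor of E-protein transcription factors (-4.64 ± 0.74, adjusted p = 0.00537, 0, 0.466 and 13.8 FPKM in WT tumor and 96.9, 49.2, 78.1 and 58.4 in spleen). Also lower were the G protein-coupled receptor gene Gpr83, part of the Treg signature (-3.36 ± 0.61, adjusted p = 0.0127, 3.23 ± 3.66 against 32.2 ± 11.3 FPKM), and the survival gene Bcl2 (-2.36 ± 0.43, adjusted p = 0.0135, 8.64 ± 4.26 against 48.5 ± 19.9 FPKM). In all, 183 of 9616 tested genes passed, 115 higher and 68 lower in WT tumor.

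By groups fixed beforehand, 9 of 23 lists passed the camera test. Of 20 immediate early and heat shock genes, 9 rose and none fell, and 14 rose adjusted over the list alone (list median 1.71, adjusted p = 2.78e-19). Besides Fos they included Dusp1, a phosphatase that ends MAP kinase signals (4.61 ± 0.64, adjusted p = 0.00273), and the chaperone gene Hsp90aa1 (1.99 ± 0.19, adjusted p = 0.000241). Rgs2, which dampens G protein signals, rose as well (5.33 ± 0.74, adjusted p = 0.00273). Of 33 effector and tumor Treg genes 6 rose and 27 did not pass, 16 rising adjusted over the list alone (1.38, adjusted p = 9.65e-11). Among 22 glycolysis genes 6 rose, 11 adjusted over the list alone (1.12, adjusted p = 1.78e-08). They included Ldha, which makes lactate (1.23 ± 0.21, adjusted p = 0.0104), and Pkm, which makes pyruvate (1.16 ± 0.20, adjusted p = 0.0106). The hypoxia response list had 3 of 18 higher and 12 adjusted over the list alone (1.24, adjusted p = 1.14e-08). It shares Ldha, Slc2a1, Pgk1, Pdk1, Aldoc, Pfkfb4 and Gpi1 with the glycolysis list, so the 2 results are not independent. Type I interferon response genes had 2 of 29 higher, 4 adjusted over the list alone (1.04, adjusted p = 3.11e-07). Ifit3, which restrains viral RNA, rose by 3.55 ± 0.79, adjusted p = 0.0356. T cell receptor and NF-kB response genes, a list that shares Egr1 and Nr4a1 with the immediate early list, had 2 of 22 higher. Adjusted over the list alone 8 were higher and 2 lower (1.07, adjusted p = 0.000435). The early activation marker Cd69 rose by 2.86 ± 0.65, adjusted p = 0.0372. Chemokines and their receptors had 2 of 18 higher, 5 higher and 1 lower adjusted over the list alone (1.04, adjusted p = 0.000643). Cxcr4, the CXCL12 receptor, rose by 3.33 ± 0.66, adjusted p = 0.0209.

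Of 18 resting and central Treg genes 3 fell and 1 rose in WT tumor against spleen, 6 and 1 adjusted over the list alone (median -0.88, adjusted p = 0.000850). The cytoplasmic ribosomal proteins were lower too (78 tested, 5 fell and 0 rose, 11 fell adjusted over the list alone, median -0.25, adjusted p = 1.43e-08). Id3 and Bcl2 were among the resting genes that fell, while Klf2, which keeps T cells in circulation through S1pr1, rose (1.64 ± 0.26, adjusted p = 0.00527, 1080.0 ± 123 against 363 ± 147 FPKM). Among ribosomal proteins Rpl8 fell by 0.66 ± 0.10 (adjusted p = 0.00523). All 9 lists also passed with an estimated correlation, at adjusted p from 0.00116 to 0.0288. Of the mitochondrial genome's own transcripts the tRNA mt-Tf rose (5.17 ± 0.50, adjusted p = 0.000241). Of its 9 tested respiratory chain genes 1 rose and 1 fell, the latter the complex I gene mt-Nd6 (-1.10 ± 0.16, adjusted p = 0.00273).

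Transcripts of other cells also differed between WT tumor and spleen. The macrophage or monocyte score (mean log2(FPKM + 1)) was 0.978 ± 0.501 in WT tumor and 2.98 ± 0.345 in spleen (-2.003, exact p = 0.0286). Of its tested members 4 of 9 fell, among them the adaptor gene Tyrobp (-5.53 ± 0.71, adjusted p = 0.00187, 3.48 ± 2.83 against 174 ± 40.4 FPKM), the complement gene C1qb (-5.77 ± 0.97, adjusted p = 0.00873) and the lipid carrier Apoe (-4.66 ± 0.75, adjusted p = 0.00593). B cell markers differed by -1.60, exact p = 0.0286 (3 of 9 lower). The MHC class II chaperone gene H2-DMb2 fell (-4.93 ± 0.77, adjusted p = 0.00530, 0.0630, 0 and 0.0930 FPKM in WT tumor and 24.5, 53.8, 56.1 and 12.1 in spleen). The conventional helper T cell score differed by 1.02, exact p = 0.0286, and neutrophil by 0.29, exact p = 0.0286. The neutrophil score was 0.215, 0.288 and 0.600 in WT tumor 2 to 4, so WT tumor 4 added much of its difference. Dendritic markers differed by -0.58, exact p = 0.0571, CD8 T or NK by 0.49, exact p = 0.114, and erythroid by -0.80, exact p = 0.686. Melanoma markers differed by -0.04, exact p = 0.6, and fibroblast or endothelial by -0.09, exact p = 0.457. The erythroid score was 2.83 in WT tumor 2 and 6.53 and 6.25 in WT tumor 3 and 4, and without WT tumor 2 its difference was 0.39. Without spleen 1 the melanoma difference was 0.01. Adjusted over the lists no score had p below 0.0571, and 0.0286 is the smallest exact p that 3 and 4 libraries allow. Short noncoding RNA differed as well: of the genes past the threshold 10 were small RNA genes (8 higher in WT tumor) and 6 mitochondrial tRNA or rRNA genes (5 higher). Nuclear small RNA made up 2.64 ± 0.386% of all FPKM in WT tumor and 1.71 ± 0.218% in spleen, and mitochondrial tRNA 0.689 ± 0.0186% and 0.462 ± 0.0643%. The count of genes past the threshold fell to 82, 89 and 111 without WT tumor replicates 2, 3 and 4, and was 107 with array weights, 112 without the filter and 87 in a fit of these 2 groups only. Named calls were lost (adjusted limma p in brackets) without WT tumor 2 for Pkm (0.0529), Bcl2 (0.0529), Cxcr4 (0.0544), Ifit3 (0.0732) and Cd69 (0.1004). Without WT tumor 3 they were lost for Ldha (0.0515), Cxcr4 (0.0799), Ifit3 (0.136) and Cd69 (0.0896). They were lost without WT tumor 4 for Ifit3 (0.0775) and Cd69 (0.116), without spleen 2 for Cd69 (0.0666) and without spleen 3 for Ifit3 (0.0838). Every WT tumor value lay beyond every spleen value in 1109 genes (11.5%), where 5.71% would be met by chance.

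**Figure D2:**
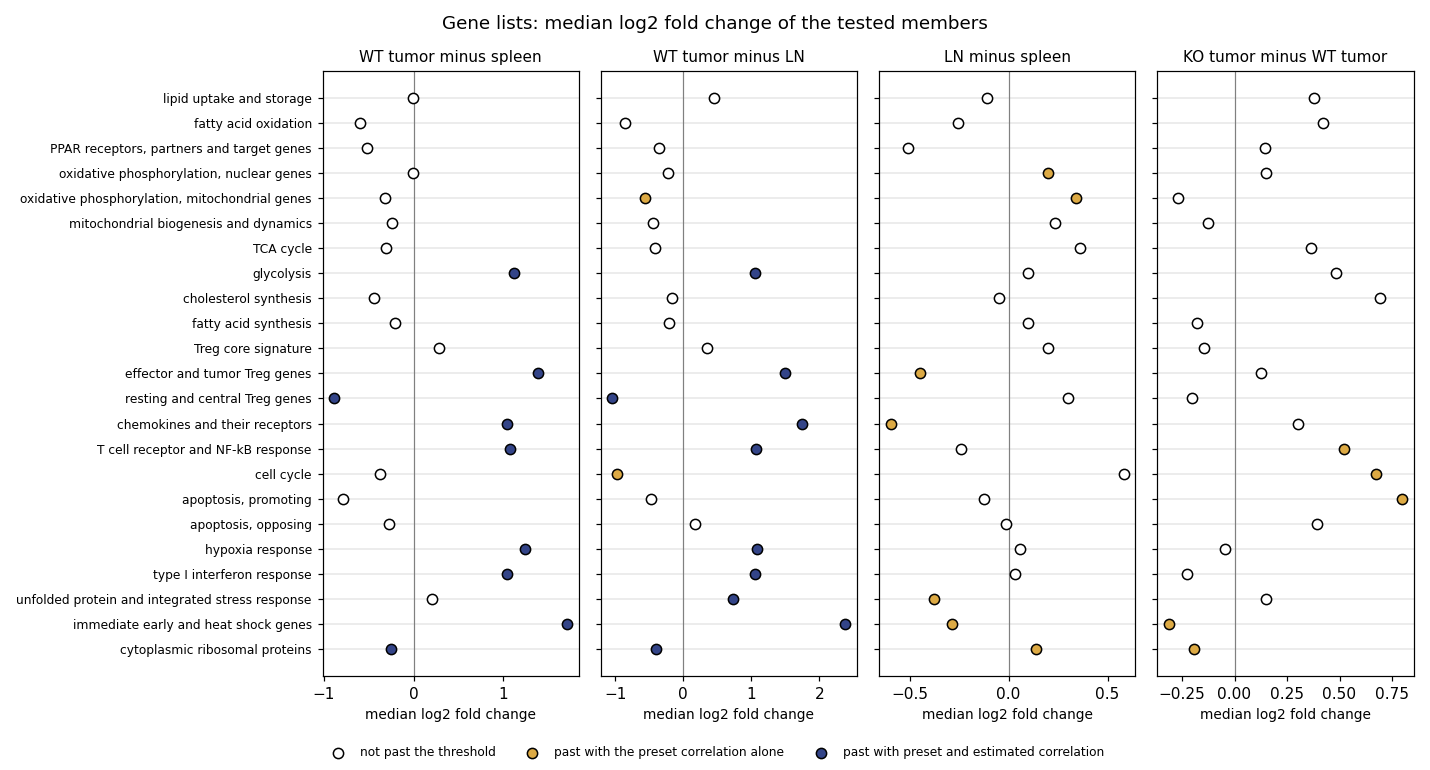
Median log2 fold change (x axis, log2(FPKM + 1) scale, with its own range in each panel) of the tested members of 23 gene lists (y axis), 1 point per list, in the 4 comparisons of spleen (n = 4), LN (n = 4), WT tumor (n = 3) and KO tumor (n = 3). Open points did not pass the camera test at adjusted p of 0.05, ochre points passed with the preset correlation alone, and blue points with preset and estimated correlation.

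Against LN, WT tumor Tregs differed in 292 of 9616 genes, 182 higher and 110 lower (n = 3 and 4), which continues the tissue question. Immediate early genes rose here too: Fos (7.39 ± 0.72, adjusted p = 9.05e-05, 637 ± 164 against 4.53 ± 5.33 FPKM) and its AP-1 partner Jun (5.06 ± 0.57, adjusted p = 0.000232, 81.1 ± 33.9 against 1.39 ± 0.727 FPKM). The orphan nuclear receptor gene Nr4a2, induced by T cell receptor signals, rose by 5.20 ± 0.63, adjusted p = 0.000391, 49.99 ± 15.6 against 0.385 ± 0.415 FPKM. Areg rose by 5.99 ± 0.61, adjusted p = 0.000105, at 0, 0, 0 and 0.359 FPKM in the LN libraries. Hsp90aa1 rose by 3.18 ± 0.19, adjusted p = 1.29e-06, 1469 ± 314 against 160.1 ± 19.3 FPKM. Effector Treg genes rose with them: Klrg1, a receptor of terminally differentiated Tregs (3.65 ± 0.61, adjusted p = 0.00420, 92.2 ± 10.1 against 8.45 ± 6.93 FPKM), and Tnfrsf9 (2.85 ± 0.35, adjusted p = 0.000436). So did Id2 (2.49 ± 0.30, adjusted p = 0.000391, 454 ± 82.2 against 79.3 ± 5.41 FPKM), the E-protein inhibitor of effector cells. Its relative Id3 fell by 5.65 ± 0.74 (adjusted p = 0.000698, 0, 0.466 and 13.8 FPKM in WT tumor and 205, 120.3, 85.7 and 175 in LN). Also lower were Igfbp4, an IGF-binding protein of naive T cells (-4.69 ± 0.59, adjusted p = 0.000559), and the receptor gene Treml2 (-4.42 ± 0.52, adjusted p = 0.000343). So were Gfer, a sulfhydryl oxidase of mitochondrial import (-4.03 ± 0.65, adjusted p = 0.00311), and Gpr83 (-3.91 ± 0.61, adjusted p = 0.00238).

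Of the 23 lists 12 passed against LN. The immediate early and heat shock genes led (20 tested, 12 rose, 16 adjusted over the list alone, median 2.38, adjusted p = 2.84e-23). Effector and tumor Treg genes were higher as well (33 tested, 11 rose, 17 adjusted over the list alone, 1.49, adjusted p = 1.27e-14). Chemokines and their receptors had 4 of 18 higher, 7 adjusted over the list alone (1.74, adjusted p = 1.03e-06). They included Ccl5, which draws T cells and monocytes (3.08 ± 0.40, adjusted p = 0.000645), and Cxcr4 (3.60 ± 0.66, adjusted p = 0.00831). Glycolysis genes had 5 of 22 higher, 8 adjusted over the list alone (1.06, adjusted p = 7.41e-08), among them Aldoa (2.41 ± 0.33, adjusted p = 0.00117) and Pkm (1.78 ± 0.20, adjusted p = 0.000232). Hypoxia response genes had 2 of 18 higher, 8 adjusted over the list alone (1.08, adjusted p = 4.85e-08). The oxygen-sensing factor Hif1a rose by 1.999 ± 0.37, adjusted p = 0.00820. T cell receptor and NF-kB response genes had 3 of 22 higher, 8 higher and 1 lower adjusted over the list alone (1.06, adjusted p = 2.71e-05). Type I interferon response genes had 3 of 29 higher, 9 adjusted over the list alone (1.06, adjusted p = 6.40e-08). The antiviral gene Rsad2 rose (3.65 ± 0.69, adjusted p = 0.00959, 40.8, 15.4 and 5.88 FPKM in WT tumor and 1.01, 0.314, 0 and 0.202 in LN). The unfolded protein and integrated stress response had 1 of 17 higher, 3 adjusted over the list alone (0.72, adjusted p = 0.000458). The member that rose was Ppp1r15a, the stress-induced eIF2α phosphatase subunit (3.57 ± 0.84, adjusted p = 0.0348). These 8 lists kept their call with an estimated correlation, the highest adjusted p being 0.00932.

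Lower than in LN were ribosomal proteins (78 tested, 14 fell and 1 rose, 30 and 1 adjusted over the list alone, median -0.40, adjusted p = 1.21e-14, and 0.00743 with an estimated correlation). Rpl10 (-0.89 ± 0.12, adjusted p = 0.000816) and Rps26 (-0.90 ± 0.14, adjusted p = 0.00205) were among them. Resting and central Treg genes had 18 tested and 4 lower (8 adjusted over the list alone, -1.04, adjusted p = 3.31e-05, and 0.00844 with an estimated correlation). In the latter Bcl2 fell (-2.53 ± 0.43, adjusted p = 0.00481), and Klf2 rose (1.70 ± 0.26, adjusted p = 0.00205, 2 rose adjusted over the list alone). Mitochondrially encoded respiratory chain genes had 2 of 9 lower, 4 adjusted over the list alone (-0.56, adjusted p = 0.000430), and adjusted p = 0.133 with an estimated correlation. The complex I gene mt-Nd6 fell (-1.52 ± 0.16, adjusted p = 0.000105). The cell cycle list had 31 tested and 0 past the limma test (median -0.98, adjusted p = 0.00336), and adjusted p = 0.0900 with an estimated correlation. Its mitotic kinase gene Plk1 stood at -2.96 ± 0.84, adjusted p = 0.0819, with 0, 0.0680 and 1.07 FPKM in WT tumor and 2.43, 10.04, 13.5 and 18.3 in LN. Lipid uptake and storage, the list closest to the target gene, did not pass (0.45, adjusted p = 0.433), though 2 of 16 members rose and 1 fell (3 and 2 adjusted over the list alone). Dgat1, which closes triglyceride synthesis (4.24 ± 0.63, adjusted p = 0.00190, 202 ± 103 against 11.8 ± 8.56 FPKM), and Lipe, hormone-sensitive lipase (2.81 ± 0.46, adjusted p = 0.00376, 74.2 ± 27.0 against 9.79 ± 4.69 FPKM), rose. Against spleen the estimate for Lipe was 1.80 ± 0.46, adjusted p = 0.0725. The mitochondrial tRNA genes mt-Tv (6.29 ± 0.45, adjusted p = 6.47e-06, 354 ± 91.3 against 3.59 ± 1.36 FPKM) and mt-Tf (5.37 ± 0.50, adjusted p = 5.98e-05) rose.

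The macrophage score differed between WT tumor and LN by 0.08, exact p = 0.8, and the B cell score by -0.10, exact p = 0.771. Without WT tumor 2 these were -0.20 and 0.18, and the erythroid difference, below, was 3.45. The receptor gene Lilrb4a, carried by myeloid cells and activated T cells, rose (5.19 ± 0.69, adjusted p = 0.000783, 69.8 ± 25.1 against 1.19 ± 1.36 FPKM). CD8 T or NK markers differed by 1.11, exact p = 0.0286 (1 of 5 higher), and helper T markers by 0.75, exact p = 0.0286. Erythroid markers differed by 2.26, exact p = 0.171 (1 of 4 higher), and dendritic by 0.19, exact p = 0.114. Neutrophil markers differed by 0.26, exact p = 0.0857, melanoma by 0.06, exact p = 0.4, and fibroblast or endothelial by -0.10, exact p = 0.0286. Adjusted over the lists no score had an exact p below 0.0952. Of the genes past the threshold 23 were small RNA genes (22 higher in WT tumor) and 10 mitochondrial tRNA or rRNA genes (9 higher), and nuclear small RNA made up 1.46 ± 0.210% and mitochondrial tRNA 0.352 ± 0.0645% of all FPKM in LN. The count of genes was 184 without LN replicate 2 and 183 without WT tumor replicate 3. After scaling to the protein-coding total it split into 162 higher and 153 lower, where the unscaled values gave 182 and 110. The Ppp1r15a call was lost (adjusted limma p in brackets) without LN 1 (0.0768), LN 2 (0.0971) and LN 4 (0.0957). It was also lost without WT tumor 2 (0.0828), WT tumor 3 (0.121) and WT tumor 4 (0.0850). Every WT tumor value lay beyond every LN value in 1632 genes (17.0%), with 5.71% by chance.

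Fos, Areg, Tnfrsf9, Hsp90aa1, Klf2 and Cxcr4 were higher, and Id3, Gpr83 and Bcl2 lower, in WT tumor than in both spleen and LN. Over all tested genes 83 passed as higher and 33 as lower in both comparisons, 116 together, and 0 passed in opposite directions. Independent lists of the same sizes would share 2.18 higher and 0.778 lower genes. Both comparisons use the same 3 WT tumor libraries, which makes their errors move together: 100 simulations of unchanged groups with that sharing gave a mean of 1.05 shared calls and a highest of 5. Genes were drawn independently there, so shared calls from genes that move together are not covered. The log2 differences correlated at 0.679 (0.643 in the simulations), with a covariance of 0.794 (0.443). With 3 WT tumor libraries these cannot be divided into separate sets of 2, so part of the excess may come from the shared libraries. The shared count was 58 without WT tumor replicate 2, 63 without WT tumor replicate 3, and 76 with array weights.

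LN and spleen Tregs, the remaining tissue pair, differed in 48 of 9616 genes, 14 higher and 34 lower in LN (n = 4 and 4), and the largest named falls were in genes of myeloid or antigen-presenting cells. Fcer1g, the signalling chain of Fc receptors (-6.33 ± 0.999, adjusted p = 0.0143, 0.202 ± 0.112 against 113 ± 79.5 FPKM), and Tyrobp (-5.80 ± 0.66, adjusted p = 0.00378, 3.02 ± 2.99 against 174 ± 40.4 FPKM) were lower in LN. The MHC class II gene H2-Eb1 was lower as well (-5.54 ± 0.81, adjusted p = 0.00982, 0.952 ± 1.37 against 93.8 ± 59.2 FPKM). Of genes that T cells express, Ccl5 was lower (-2.26 ± 0.37, adjusted p = 0.0169, 271 ± 176 against 1123 ± 259 FPKM), as was Hsp90aa1 (-1.19 ± 0.17, adjusted p = 0.00982, 160.1 ± 19.3 against 365 ± 30.5 FPKM). Pradc1, a secreted glycoprotein, was higher in LN (3.66 ± 0.55, adjusted p = 0.0106, 10.4, 18.5, 16.6 and 17.1 FPKM in LN and 1.57, 0, 0.0580 and 0 in spleen). So was mt-Co1, a subunit of complex IV (0.66 ± 0.11, adjusted p = 0.0267, 1321 ± 136 against 836 ± 39.4 FPKM). The macrophage score differed by -2.09, exact p = 0.0286 (5 of 9 tested lower), B cell by -1.50, exact p = 0.0286 (2 of 9 lower), and erythroid by -3.06, exact p = 0.0286 (1 of 4 lower). Dendritic markers differed by -0.76, exact p = 0.0286 (1 of 7 lower), CD8 T or NK by -0.62, exact p = 0.0571, and helper T by 0.27, exact p = 0.429. Melanoma markers differed by -0.10, exact p = 0.229, neutrophil by 0.03, exact p = 0.743, and fibroblast or endothelial by 0.01, exact p = 0.8. The neutrophil difference was -0.02 without LN 4, and the fibroblast or endothelial one -0.05 without spleen 2 and below 0 without spleen 4. Adjusted over the lists no score had an exact p below 0.0714.

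Camera passed 7 lists between LN and spleen, and none passed with an estimated correlation. Nuclear respiratory chain genes were higher in LN (76 tested, 0 past the limma test, median 0.20, adjusted p = 0.00992, adjusted p = 0.0748 with an estimated correlation), with Ndufb4 at 1.22 ± 0.42, adjusted p = 0.284. So were the mitochondrial ones (9 tested, 1 rose, 1 higher and 0 lower adjusted over the list alone, 0.34, adjusted p = 0.00139, adjusted p = 0.228 with an estimated correlation). Ribosomal proteins (78 tested, 0 rose and 1 fell, 12 and 5 adjusted over the list alone, 0.14, adjusted p = 0.00231, adjusted p = 0.251 with an estimated correlation) went both ways. Rps6 stood at 0.86 ± 0.18, adjusted p = 0.0594 and Rps21 at -0.69 ± 0.11, adjusted p = 0.0143. Lower in LN were effector and tumor Treg genes (33 tested, 0 past the limma test, 0 higher and 0 lower adjusted over the list alone, -0.45, adjusted p = 0.0407, adjusted p = 0.228 with an estimated correlation). Klrg1 stood at -1.89 ± 0.57, adjusted p = 0.210 and the inhibitory receptor Lag3 at -2.43 ± 0.69, adjusted p = 0.182. Chemokines and their receptors were lower in LN (18 tested, 1 fell, 2 adjusted over the list alone, -0.60, adjusted p = 0.0423, adjusted p = 0.167 with an estimated correlation). The unfolded protein response was lower too (17 tested, 0 past the limma test, -0.38, adjusted p = 0.0451, adjusted p = 0.167 with an estimated correlation). The ER chaperone gene Hspa5 stood at -1.34 ± 0.38, adjusted p = 0.176. Immediate early and heat shock genes had 1 of 20 lower, 3 adjusted over the list alone (-0.28, adjusted p = 0.00231, adjusted p = 0.167 with an estimated correlation). At unadjusted limma p below 0.05 there were 997 genes in all, where 480.8 would be met by chance.

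The count of genes for LN vs spleen was 29, 29, 13, 18, 23 and 31 without spleen 2, spleen 4, LN 1, LN 2, LN 3 and LN 4. It was 16 without the filter, 27 over protein-coding genes only and 29 without the other-cell genes. Lost calls (adjusted limma p in brackets) were Fcer1g without LN 1 (0.0511) and Ccl5 without spleen 4 (0.0513). Rps21 was lost without LN 1 (0.0511) and LN 2 (0.0544). The mt-Co1 call was lost without spleen 2 (0.0608), spleen 3 (0.0518), spleen 4 (0.0640), LN 1 (0.0511), LN 2 (0.0683), LN 3 (0.0725) and LN 4 (0.0692). Rps6 passed without spleen 3 (limma adjusted p = 0.0440). Among lists, chemokines were lost without spleen 1, 2 or 3 and LN 1 or 3 (adjusted camera p 0.0665, 0.0520, 0.0628, 0.0693 and 0.0707 in that order). Effector Treg genes were lost without spleen 1 and LN 1 or 3 (adjusted camera p 0.185, 0.0883 and 0.0964 in that order). The unfolded protein response was lost without spleen 2, 3 or 4 and LN 1, 2 or 4 (adjusted camera p 0.0831, 0.118, 0.0847, 0.0834, 0.0670 and 0.0968 in that order). Without LN 1 the number of lists was 4. Every LN value lay beyond every spleen value in 757 genes (7.87%), with 2.86% by chance.

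KO tumor Tregs differed from WT tumor Tregs, the second question of the series, in 23 of 8210 genes, 8 higher and 15 lower (n = 3 and 3), of which 9 are protein-coding. Klf2 fell by 1.31 ± 0.21 (adjusted p = 0.0397, 438 ± 94.1 against 1080.0 ± 123 FPKM). Among genes of plasma cells and macrophages Jchain, which joins IgA and IgM, rose (7.15 ± 0.81, adjusted p = 0.00798, 1113, 126 and 180.4 FPKM in KO tumor and 0.535, 2.14 and 0.847 in WT tumor). So did C1qb (5.46 ± 0.65, adjusted p = 0.00952, 67.9 ± 29.0 against 0.476 ± 0.304 FPKM) and Tyrobp (5.08 ± 0.67, adjusted p = 0.0158, 129 ± 43.8 against 3.48 ± 2.83 FPKM). The calcium-binding S100a1 rose (4.75 ± 0.74, adjusted p = 0.0397, 19.7, 66.4 and 25.8 FPKM in KO and 0, 0 and 0.9 FPKM in WT tumor). Ergic3, of transport between ER and Golgi, rose as well (3.47 ± 0.49, adjusted p = 0.0222, 79.3 ± 16.7 against 6.33 ± 2.09 FPKM). Most of the lower genes were noncoding. There were 7 mitochondrial tRNA or rRNA genes, such as mt-Ta (-3.35 ± 0.36, adjusted p = 0.00673, 26.2 ± 9.15 against 266 ± 11.97 FPKM), mt-Tv (-3.03 ± 0.33, adjusted p = 0.00673) and mt-Tf (-2.80 ± 0.30, adjusted p = 0.00673). The 4 small RNA genes included the nucleolar RNA Snora23 (-3.61 ± 0.36, adjusted p = 0.00673, 49.5 ± 23.1 against 583 ± 110.3 FPKM). At unadjusted limma p below 0.05 there were 709 genes, where 410.5 would be met by chance.

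Camera passed 5 lists between KO and WT tumor, none of which passed with an estimated correlation. Cell cycle genes (25 tested, 0 past the limma test and 0 higher and 0 lower adjusted over the list alone) had a median of 0.67 (adjusted p = 0.00504, adjusted p = 0.313 with an estimated correlation). Plk1 stood at 2.91 ± 0.75, adjusted p = 0.262, the replication clamp Pcna at 1.13 ± 0.43, adjusted p = 0.489 and Mki67 at 1.61 ± 0.63, adjusted p = 0.513. T cell receptor and NF-kB response genes (22 tested, 0 past, 0 higher and 0 lower adjusted over the list alone) had 0.52 (adjusted p = 0.0131, adjusted p = 0.313 with an estimated correlation). Nr4a1 stood at 1.76 ± 0.64, adjusted p = 0.460 and Rel at 1.196 ± 0.49, adjusted p = 0.552. Apoptosis-promoting genes (19 tested, 0 past, 0 higher and 0 lower adjusted over the list alone) had 0.80 (adjusted p = 0.0434, adjusted p = 0.313 with an estimated correlation). The death receptor Fas stood at 2.097 ± 0.72, adjusted p = 0.425 and Bak1 at 1.38 ± 0.59, adjusted p = 0.561. Ribosomal proteins (76 tested, 1 fell, 0 higher and 1 lower adjusted over the list alone) had -0.19 (adjusted p = 1.78e-07, adjusted p = 0.313 with an estimated correlation). Rps21 was the member that fell (-0.94 ± 0.13, adjusted p = 0.0227), and Rps14 stood at -0.65 ± 0.14, adjusted p = 0.173. Immediate early and heat shock genes (22 tested, 0 past, 1 lower adjusted over the list alone) had -0.31 (adjusted p = 0.0434, adjusted p = 0.367 with an estimated correlation). Hsp90aa1 stood at -0.84 ± 0.19, adjusted p = 0.176 and Dnajb1 at -1.11 ± 0.31, adjusted p = 0.295.

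The metabolic lists closest to Cd36 did not pass between KO and WT tumor. Lipid uptake and storage had 0 of 15 members past the limma test, 3 higher adjusted over the list alone (median 0.38, adjusted p = 0.261). The fatty acid-binding protein gene Fabp5 stood at 3.84 ± 1.03, adjusted p = 0.277, 35.0 ± 30.4 against 0.955 ± 1.46 FPKM and Gpat4, the first enzyme of glycerolipid synthesis, at 3.15 ± 0.69, adjusted p = 0.161, 11.3 ± 3.41 against 0.374 ± 0.291 FPKM. Fatty acid oxidation (21 tested, 0.42, adjusted p = 0.981) had Etfa, of electron transfer, at 2.34 ± 0.85, adjusted p = 0.460. PPAR receptors, partners and targets (13 tested, 0.14, adjusted p = 0.981) had the uncoupling protein gene Ucp2 at 0.93 ± 0.52, adjusted p = 0.705. The Treg core signature stood at adjusted p = 0.997, 1 member higher adjusted over the list alone, Cd83 (1.87 ± 0.43, adjusted p = 0.194, 111 ± 24.4 against 30.7 ± 11.2 FPKM).

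Macrophage scores were 2.71 ± 0.313 in KO and 0.978 ± 0.501 in WT tumor (1.73, exact p = 0.1, 2 of 8 tested higher). Whether this difference bears on the list results above was not tested. Melanoma markers scored 0.441 and 0.179 (0.26, exact p = 0.1), of which S100a1 was the tested member. S100a1 alone carried this difference, while Mlana, Tyrp1, Dct, Sox10 and Oca2 were listed at 0 in every library. B cell scores differed by -0.02, exact p = 1, CD8 T or NK by 0.15, exact p = 0.2, and helper T by 0.15, exact p = 0.1. Dendritic markers differed by 0.16, exact p = 0.9, neutrophil by -0.08, exact p = 0.6, erythroid by -0.05, exact p = 1, and fibroblast or endothelial by 0.26, exact p = 0.3, where 0.1 is the smallest exact p of 3 and 3 libraries. Erythroid scores lay apart within both groups, at 6.34, 6.87 and 2.26 in KO tumor 1 to 3 and 2.83, 6.53 and 6.25 in WT tumor 2 to 4. Their difference was 1.40 without KO tumor 3 and -1.24, 0.62 and 0.48 without WT tumor 2, 3 and 4. It was -0.64 and -0.91 without KO tumor 1 and 2. The B cell difference turned to 0.23, 0.06 and 0.18 without WT tumor 4, KO tumor 1 and KO tumor 2, and to 0.00 without WT tumor 3. Without KO tumor 1 the dendritic difference was -0.08, and without WT tumor 4 the neutrophil one 0.03. The mitochondrial tRNA share of all FPKM was 0.229 ± 0.0202% in KO and 0.689 ± 0.0186% in WT tumor, where spleen had 0.462 ± 0.0643% and LN 0.352 ± 0.0645%. The count of genes was 14, 14 and 14 without WT tumor 2, 3 and 4, and 15, 9 and 9 without KO tumor 1, 2 and 3. It was 7 over protein-coding genes only, 60 in a fit of all 14 libraries, and 0 without the filter, where limma tested 15208 genes. Jchain, mt-Ta, mt-Tv, mt-Tf and Snora23 passed whichever of the 6 libraries was left out. Under other settings the limma adjusted p rose as far as 0.0538 for Jchain, 0.0707 for mt-Ta and mt-Tv, 0.0806 for mt-Tf and 0.183 for C1qb. Every KO value lay beyond every WT tumor value in 1188 genes (14.5%), with 10% by chance.

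The other calls of KO tumor vs WT tumor depended on single libraries (adjusted limma p in brackets). Tyrobp was lost without KO tumor 1 (0.0643), KO tumor 2 (0.1496) and KO tumor 3 (0.160). S100a1 was lost without WT tumor 2 (0.0992), WT tumor 3 (0.0978) and WT tumor 4 (0.0655). Ergic3 was lost without WT tumor 3 (0.0587), WT tumor 4 (0.0625), KO tumor 1 (0.1501), KO tumor 2 (0.222) and KO tumor 3 (0.191). Klf2 was lost without WT tumor 2 (0.146), WT tumor 3 (0.0871), WT tumor 4 (0.0995), KO tumor 2 (0.202) and KO tumor 3 (0.212). Rps21 was lost without WT tumor 2 (0.0848), WT tumor 3 (0.0587), KO tumor 1 (0.0649), KO tumor 2 (0.1496) and KO tumor 3 (0.186). C1qb and S100a1 fell below the filter when a KO library was left out. Of the lists, cell cycle genes and ribosomal proteins passed in all 6. The T cell receptor list was lost without WT tumor 4 or KO tumor 3 (adjusted camera p 0.0720 and 0.0605 in that order). Apoptosis-promoting genes were lost without each of the 6 (adjusted camera p 0.0848, 0.126, 0.128, 0.0569, 0.258 and 0.189 in that order). Immediate early genes were lost without WT tumor 3 or 4 or any KO library (adjusted camera p 0.173, 0.0720, 0.0705, 0.104 and 0.0605 in that order). The number of lists past the threshold was 3, 2, 3, 3 and 2 without WT tumor 3 and 4 and KO tumor 1, 2 and 3.

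**Figure D3:**
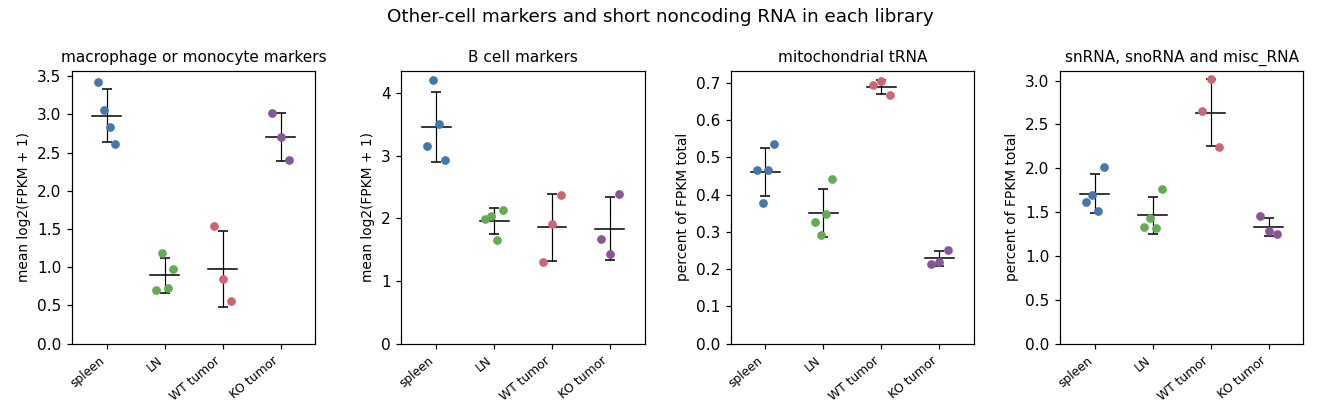
Mean log2(FPKM + 1) of macrophage or monocyte and of B cell markers (left pair of panels), and percent of the FPKM total in mitochondrial tRNA and in snRNA, snoRNA and misc_RNA genes (right pair), by group on the x axis. The last panel also counts scaRNA and nuclear rRNA genes. Points are libraries (spleen 4, LN 4, WT tumor 3, KO tumor 3), horizontal lines means and vertical bars the SD.

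Of genes that separate WT tumor from spleen Tregs, Klf2 had the opposite sign between KO and WT tumor. Ergic3 (-2.67 against spleen, limma adjusted p = 0.0234), Tyrobp, C1qb, mt-Ta, mt-Tv and mt-Tf also passed in both comparisons with opposite signs. Both comparisons use the same WT tumor libraries, and a deviation of these alone gives opposite signs. Hsp90aa1 had the opposite sign too but did not pass between KO and WT tumor (-0.84 ± 0.19, limma adjusted p = 0.176). Icos (0.47 ± 0.16, adjusted p = 0.432) and Gpr83 (-0.85 ± 0.85, adjusted p = 0.853), chosen after their values were seen, kept the sign they had against spleen and did not pass either. Over 9440 genes the covariance of the KO against WT and the WT against spleen log2 differences was -0.500. Unchanged groups that share the WT tumor libraries gave -0.448 in 100 simulations, a difference of -0.0517. By correlation the data were less opposed than the simulations, at -0.489 against -0.592. Without WT tumor replicate 3 the covariance difference was -0.0372, and with LN in place of spleen -0.108.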

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

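The predictions of the macrophage and spill-over tests and of the isolation test were written before those tests were run, and the other tests of the first pattern and all of the second were chosen after the result was seen. Immediate early and heat shock genes were higher in WT tumor than in spleen and LN libraries. If cell isolation from tumors raised them, the KO tumor libraries should carry them too, and the lowest KO tumor score lay 1.61 above the highest spleen or LN score (KO 5.98 ± 0.0785, WT 6.12 ± 0.254, spleen 3.999 ± 0.321, LN 3.55 ± 0.1004). A response of Tregs within tumors would give the same value, so isolation and biology could not be told apart. Macrophage transcripts are not a likely source, since their score was lower in WT tumor than in spleen (difference -2.003). Nor is library composition, since the 9 members past the threshold against spleen all passed after scaling to the protein-coding total, with a median of 2.59 against 2.67 before.

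Mitochondrial tRNA and small RNA genes were lower in KO than in WT tumor libraries (17 mitochondrial tRNA genes, median -2.19). The length correction of short genes in FPKM is unlikely, since 99.3% of 2073 low values of genes under 150 bp were whole reads at the annotated length. The equally short T cell receptor J segments had a median of 0.52 (35 genes, 20 above 0, SD 2.17). They spread too widely to decide this by themselves. The 11 called genes held 6 mitochondrial tRNA genes, 4 small RNA genes and a mitochondrial rRNA gene. After scaling to the protein-coding total 10 of the 11 still passed, which does not leave room for composition alone. A difference in the yield of all short noncoding RNAs between these libraries would also lower small RNA genes that did not pass. Of these 139 genes 13.7% lay above 0 (median -1.30), where 54.9% of protein-coding genes did. Mitochondrial rRNA genes were not part of that check. Nuclear small RNA shares were 2.64 ± 0.386% in WT tumor, 1.33 ± 0.106% in KO tumor, 1.46 ± 0.210% in LN and 1.71 ± 0.218% in spleen, so WT tumor stood apart, while mitochondrial tRNA (0.689, 0.229, 0.352 and 0.462%) lay above spleen and LN in WT and below them in KO tumor, and an excess in WT libraries or a deficit in KO, from preparation or genotype, were not separable here.

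Macrophage transcripts were higher in KO than in WT tumor libraries. If macrophages or their RNA entered the KO samples, a second list of abundant macrophage genes should rise as well, and its median was 0.83 (score 3.82 ± 0.398 against 2.62 ± 0.146, exact p = 0.1). The lowest KO score, 3.39, lay above the highest WT tumor score, 2.77, so the prediction written beforehand was met. Every KO value lay above every WT value in 2 of its 13 genes and 7 of 16 in the first list (5% by chance). Lyz2, a criterion chosen after, stood at 6.21, 0 and 0.368 FPKM in KO and 19.9, 0 and 0.164 in WT tumor. In spleen 1 to 4 Lyz2 was 46.9, 0.128, 3.61 and 0.206 FPKM and C1qb 134, 121, 42.4 and 53.9. Lyz2 did not follow C1qb there and cannot decide the question. Values of 2 MHC genes in LN and spleen had been seen before the second list was fixed. The source of the transcripts was thus not settled. Spill-over from spleen libraries could not be decided: 12 other genes higher in spleen than in LN had a median of -0.57 but went both ways (SD 1.75), and some are abundant in Tregs themselves, while B cell scores, a comparison chosen after the result was seen, were 1.44 to 2.40 in KO tumor, 1.30 to 2.37 in WT tumor and 2.94 to 4.21 in spleen. Expression of these genes by KO Tregs themselves was not tested.

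In spleen and LN, the groups of 4, single libraries stood far from the other 3 by Dixon's ratio in 18 of 183 groups of values tested, where chance alone gives about 1 in 20, or 9.15. These were the share of low values that are whole reads in spleen 1 (95.6%, others 94.9 to 95.0%), the globin share in LN 3 (0.234%, others 0.0155 to 0.0183%), the helper T score in spleen 4 (0.814, others 1.48 to 1.61) and the erythroid score in LN 3 (4.91, others 2.16 to 2.48). On the log2(FPKM + 1) scale they were Aldoa in LN 4 (5.21, others 6.38 to 6.50), Apoe in LN 2 (1.81, others 0.07 to 0.27), Areg in LN 4 (0.44, others 0.00 to 0.00), Bcl2 in LN 2 (5.92, others 5.63 to 5.68), C1qb in LN 2 (4.67, others 0.23 to 0.26) and Cd83 in LN 1 (5.21, others 6.22 to 6.40). The others were Jchain in spleen 3 (5.98, others 0.00 to 0.59), Klf2 in LN 1 (8.78, others 8.202 to 8.26), Ldha in spleen 3 (7.95, others 8.61 to 8.67), Lipe in LN 3 (4.15, others 3.01 to 3.17), Pradc1 in spleen 1 (1.36, others 0.00 to 0.08), Rpl8 in LN 4 (11.75, others 12.03 to 12.04), Treml2 in spleen 4 (3.18, others 4.37 to 4.37) and mt-Ta in spleen 4 (6.95, others 5.72 to 5.90).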

How the results depend on the processing

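Alternatives over protein-coding genes only, with scaling to the protein-coding total, without other-cell genes and with a common spread in the simulation were chosen after seeing the data, the rest before. The DESeq2 alternative, which needs counts, was not run. Log2 differences of called named genes changed sign under no alternative, and median-ratio and protein-coding scaling changed none of the 98 named results, called or not. Over all libraries left out in turn 612 results kept their label, 51 calls were lost and 1 was added. Array weights kept 94, and a fit of all 14 libraries 95. Of called named genes 17 of 23 (WT tumor against spleen), 29 of 30 (WT tumor against LN), 4 of 8 (LN against spleen) and 5 of 11 (KO against WT tumor) passed whichever library was left out. With both scalings, array weights, the fit of all 14 libraries and the replicate number as a block added, 17, 29, 4 and 1 passed throughout. For WT tumor against spleen 183 genes became 112 without the filter, 107 with array weights, 87 with only the 2 groups, and 82 to 173 leaving out 1 library. For WT tumor against LN 292 became 183 to 268 leaving out 1. For LN against spleen 48 became 16 without the filter, 27 over protein-coding genes, 29 without other-cell genes, and 13 to 35 leaving out 1. For KO against WT tumor 23 became 0 without the filter (limma), 7 over protein-coding genes, 60 with all 14 libraries, and 9 to 15 leaving out 1. The 116 genes shared by both tumor comparisons became 76 with array weights and 58 to 110 leaving out 1. Without the filter and over protein-coding genes other sets of genes were tested. Where libraries were left out fewer samples entered, and for the rest the cause was not tested. Lists numbered 9 to 11 against spleen and 10 to 14 against LN under all settings. For LN against spleen 7 became 0 with an estimated correlation, 2 with fry and 4 to 7 leaving out 1. For KO against WT tumor 5 became 0 with an estimated correlation and 3 with fry, of which apoptosis-promoting genes (adjusted fry p 0.00204) are 1 of the 5 and cholesterol synthesis (0.0233) and nuclear oxidative phosphorylation (0.0436) are new. The count was 2 with all 14 libraries, 3 after scaling, and 2 to 5 leaving out 1. The covariance difference of -0.0517 became -0.108 with a common spread in the simulation, -0.108 with LN in place of spleen and -0.0732 with a stricter filter, and ran from -0.0693 to -0.0372 leaving out 1, the latter without WT tumor replicate 3. Cd36 ran from -1.60 to -0.78 (LN against spleen, -1.60 without spleen 1) and from 0 to 0.52 (KO against WT tumor, 0 without KO tumor 2).

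Replicate numbers are not said to pair samples. With the number as a block, the counts were 89, 186, 20 and 6 genes (WT tumor against spleen, against LN, LN against spleen, KO against WT tumor), 62 shared genes and 3 lists for KO against WT tumor, and 83 of the 98 named results kept their label. A block uses up residual degrees of freedom, and no pairing showed in the data: residuals of 18 same-numbered pairs correlated at -0.0276 to 0.0301 and those of 55 others at -0.0327 to 0.0299. Depth limits the low end: in the library with the fewest reads 3 reads of the Cd36 transcript are 0.0822 FPKM, and in that with the most 0.0320. Genes at 10 FPKM or more in 1 library and listed at 0 in another of the same group made up 7.48% (spleen), 4.09% (LN), 4.88% (WT tumor) and 3.76% (KO tumor).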

Other observations

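Mitochondrial transcripts fell into classes that differed by group. Mitochondrial rRNA, the core of the organelle's ribosome, made up 8.51 ± 0.211% of all FPKM in WT tumor (mean ± SD), 6.90 ± 0.265% in KO tumor, 6.54 ± 0.418% in spleen and 5.10 ± 0.119% in LN. Mitochondrial mRNA, which encodes respiratory chain subunits, ran the other way, 2.06 ± 0.286% in LN, 1.52 ± 0.190% in spleen, 1.32 ± 0.0981% in KO and 1.22 ± 0.102% in WT tumor. Mitochondrial tRNA stood at 0.352 ± 0.0645% in LN, 0.462 ± 0.0643% in spleen, 0.689 ± 0.0186% in WT tumor and 0.229 ± 0.0202% in KO tumor. Nuclear small RNA (snRNA, snoRNA, scaRNA, misc_RNA and nuclear rRNA genes) stood at 1.46 ± 0.210%, 1.71 ± 0.218%, 2.64 ± 0.386% and 1.33 ± 0.106% in the same order.

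Lists that did not pass camera are given here as list median and adjusted p in brackets. Against spleen, WT tumor had lipid uptake and storage -0.01 (0.344), fatty acid oxidation -0.60 (0.105), PPAR genes -0.51 (0.257), TCA cycle -0.31 (0.332), mitochondrial biogenesis -0.24 (0.584), cholesterol synthesis -0.44 (0.433), fatty acid synthesis -0.21 (0.673), nuclear oxidative phosphorylation -0.01 (0.673), mitochondrial oxidative phosphorylation -0.31 (0.319), cell cycle -0.38 (0.120), unfolded protein response 0.21 (0.120), Treg core signature 0.28 (0.0537), apoptosis-promoting -0.79 (0.433), apoptosis-opposing -0.27 (0.612). Of the Treg core signature 3 of 23 members rose and 1 fell, 5 and 3 adjusted over the list alone, Tnfrsf9 and Gpr83 among them. Lipid uptake had 4 members higher adjusted over the list alone. Against LN, WT tumor had fatty acid oxidation -0.85 (0.140), PPAR genes -0.36 (0.455), TCA cycle -0.42 (0.0625), mitochondrial biogenesis -0.44 (0.433), cholesterol synthesis -0.17 (0.512), fatty acid synthesis -0.21 (0.534), nuclear oxidative phosphorylation -0.23 (0.0818), Treg core signature 0.35 (0.255), apoptosis-promoting -0.48 (0.455), apoptosis-opposing 0.17 (0.547). There the Treg core signature had 2 higher and 1 lower, 6 and 1 adjusted over the list alone, and the TCA cycle, which feeds the respiratory chain, 4 lower adjusted over the list alone. Leaving out 1 library gave new calls: in WT tumor vs spleen the Treg core signature without spleen 1 (adjusted camera p 0.0414) and spleen 4 (0.0148), and fatty acid oxidation without WT tumor 3 (0.0309). In WT tumor vs LN these were the TCA cycle without LN 1 (0.0381) and WT tumor 2 (0.0129), and fatty acid oxidation without WT tumor 3 (0.0471). With all libraries and an estimated correlation these lists stood at adjusted p 0.120 and 0.127 against spleen, and 0.2004 and 0.159 against LN. Other settings, with all libraries kept, gave new calls too. In WT tumor vs spleen the Treg core signature passed with median-ratio scaling (0.0398), all 14 libraries (0.0345), the replicate number as a block (0.0490) and protein-coding genes only (0.0416). The unfolded protein response passed there without the filter (0.0477), with all 14 libraries (0.0315) and with fry (0.0467), the cell cycle without the filter (0.0465) and fatty acid oxidation with fry (0.0143). In WT tumor vs LN nuclear oxidative phosphorylation passed without the filter (0.0112), after protein-coding scaling (0.00901) and with fry (8.37e-05), the TCA cycle without the filter (0.0112) and fatty acid oxidation with fry (0.0118).

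Between LN and spleen the remaining lists had lipid uptake and storage -0.11 (0.9803), fatty acid oxidation -0.25 (0.950), PPAR genes -0.51 (0.813), TCA cycle 0.36 (0.415), mitochondrial biogenesis 0.23 (0.950), cholesterol synthesis -0.05 (0.950), fatty acid synthesis 0.10 (0.950), glycolysis 0.10 (0.950), resting Treg genes 0.30 (0.185), T cell receptor and NF-kB response -0.24 (0.284), cell cycle 0.58 (0.185), hypoxia response 0.06 (0.950), type I interferon response 0.03 (0.793), Treg core signature 0.20 (0.813), apoptosis-promoting -0.13 (0.950), apoptosis-opposing -0.01 (0.950). Between KO and WT tumor they had TCA cycle 0.37 (0.376), mitochondrial biogenesis -0.12 (0.981), cholesterol synthesis 0.69 (0.0862), fatty acid synthesis -0.18 (0.905), nuclear oxidative phosphorylation 0.15 (0.905), mitochondrial oxidative phosphorylation -0.27 (0.413), glycolysis 0.49 (0.137), effector Treg genes 0.12 (0.981), resting Treg genes -0.20 (0.124), chemokines and their receptors 0.30 (0.376), apoptosis-opposing 0.39 (0.221), hypoxia response -0.05 (0.833), type I interferon response -0.23 (0.0862), unfolded protein response 0.15 (0.981). Of the resting genes Klf2 fell, and 2 hypoxia response genes were higher adjusted over the list alone. New calls were resting Treg genes in LN vs spleen without spleen 4 (adjusted camera p 0.0463) and the type I interferon response in KO tumor vs WT tumor without WT tumor 2 (0.0287). With all libraries and an estimated correlation they stood at adjusted p 0.326 and 0.406. Without the filter resting Treg genes also passed in LN vs spleen (0.0464) and the interferon response in KO tumor vs WT tumor (0.0356), the latter over protein-coding genes only as well (0.0222). With fry cholesterol synthesis (0.0233) and nuclear oxidative phosphorylation (0.0436) passed there.

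The tests against other splits of the libraries were set before they were run. For WT tumor against spleen 1 of 35 splits, the real one, gave as many as 183 genes (highest other 7). For WT tumor against LN 1 of 35 gave 292 (highest other 5), and for LN against spleen 1 of 35 gave 48 (highest other 2). No other split came near these counts, but 1 of 35 is the least that such splits can give. For the lists, 5 of 35 splits gave at least the 9 lists of WT tumor against spleen (highest other 10). At least the 12 of WT tumor against LN came from 4 of 35 (highest other 13). Other splits can keep most WT tumor libraries on the same side and so carry part of the tissue difference. These splits thus neither exclude chance for these 2 counts nor show that chance gives them. For LN against spleen 1 of 35 gave the 7 lists (highest other 3), again the least possible. These counts use the preset correlation and do not show how firmly each list passed. With an estimated correlation all 9 lists of WT tumor against spleen passed, and 0 lists for LN against spleen and for KO against WT tumor. For KO against WT tumor 10 splits are too few: the real value was 23 genes (1 split, highest other 0) and 5 lists (1 split, highest other 2). The 116 genes shared by both tumor comparisons were reached by 1 of 100 splits, the real one, and the highest other was 93. Labels of all tissues were shuffled there, so the WT tumor libraries could stay together while spleen and LN libraries changed places. Whether the split with 93 was of this kind was not recorded, so it cannot tell how near chance comes. The covariance difference (-0.0527 in this run) was matched by 16 of 100 splits (the furthest at -0.226). Spleen and tumor libraries were mixed in these splits, which can carry the tissue difference. They do not exclude chance, and cannot show that chance gives the value.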
